A study of Saccharomyces cerevisiae with 13 samples.

How the data were processed

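The series holds 13 Affymetrix-type yeast expression arrays of strain BY4741, grown to saturation in YPGE medium with glycerol and ethanol at 30°C. Per the labels, cells received 2% isopropanol, called untreated, or 0.05 mM TFM for 1, 2 or 4 h, and samples from before the treatment stand for time zero. The label of the time zero samples names 2% isopropanol as their agent, while the series design places them before any treatment, and they were taken as untreated here. Total RNA was isolated with RNeasy kits and biotin-labelled cRNA was made with an Enzo kit. Every group had 2 arrays except isopropanol at 2 h with 1, since the RNA of the other sample was of poor quality per the labels.

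The deposited table gives log2 RMA values, background-corrected, quantile normalized and summarized per probe set by the authors per the submitters' processing notes; the RMA version is not given in the sources used here. It has 5900 probe sets, of which 184 are controls, 5498 carry 1 gene and 218 carry none. The array annotation was joined to the RefSeq gene table by gene ID, which updated 12 symbols. The 47 genes with several probe sets were represented by the probe set with the highest mean over all arrays, leaving 5449 genes. The probe sets of unspiked controls reached a mean of 5.94, and 72 genes had a mean at or under it. Replicates correlated across genes at Pearson r from 0.9917 to 0.9984. Because quantile normalization gives every array the same distribution, all changes are relative and a change in total mRNA per cell cannot be seen. The number of arrays limits the precision: the median standard error of a log2 change was 0.0954 at 1 and 4 h, 0.117 at 2 h and 0.0595 for the average over time points.

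All comparisons came from 1 limma model (limma 3.58.1 in R 4.3.3) with a mean for each of the 7 groups, fitted to all 13 arrays with the default eBayes settings (6 residual and 3.52 prior degrees of freedom). The contrasts were TFM minus isopropanol at 1, 2 and 4 h and averaged over these times, isopropanol minus time zero at each time, and the TFM effect at 4 h minus that at 1 h. P-values were adjusted by the Benjamini-Hochberg method over the 5449 genes, with a threshold of 0.05, and are two-sided. The lone isopropanol 2 h array was assumed to vary like the other groups. Overlaps between gene sets were tested with Fisher's exact test, two-sided. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

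The groups, comparisons, tests, gene lists, rule for named genes and other settings to try were set before the data were examined. The rule named the 10 largest rises and 10 largest falls past the threshold in the averaged TFM contrast. At each TFM time it named the 5 largest each way whose TFM arrays all lay on one side of the isopropanol arrays, and for the difference between 4 h and 1 h the 5 largest each way. For isopropanol it named the 10 largest each way at 4 h and the 5 largest at 1 and 2 h or, where none passed, the 5 genes of smallest p. For each list it named up to 2 members each way with the smallest adjusted p in the averaged contrast, and it added the genes deleted in BY4741. Not every gene the rule named is printed.

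The 35 lists were the respiratory chain, ATP synthase, mitochondrially encoded genes, mitochondrial ribosome, tricarboxylic acid cycle, retrograde response, glyoxylate cycle and gluconeogenesis, glycolysis, hexose transporters, trehalose and glycogen, and beta-oxidation and peroxisome. They further held general stress (Msn2/Msn4), heat shock (Hsf1), oxidative stress (Yap1/Skn7), oxidoreductases and glutathione transferases, pleiotropic drug resistance (Pdr1/Pdr3), weak acid response (War1/Haa1), cytosolic ribosomal proteins, ribosome biogenesis, amino acid biosynthesis (Gcn4), sulfur assimilation and methionine, and nitrogen catabolite repressed genes. The rest were the phosphate regulon (Pho4), ergosterol biosynthesis, hypoxic genes, iron regulon (Aft1/Aft2), proteasome, unfolded protein response, autophagy, histones, cyclins and cell cycle, a-specific genes, alpha-specific genes, meiosis and sporulation, and genes deleted in BY4741. Each of the 32 lists with at least 5 measured members was tested with camera at its preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists. Gene counts within a list were also computed with the p-values adjusted over the list alone.

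Replicate deviations correlated at 0.266 to 0.599 in all 3 pairs of groups without TFM, so the replicate numbers were taken to pair these arrays, on the data alone, since the labels name no shared culture or day. The model was tested on simulated data with the same layout. At simulated log2 changes of 0.5, 1 and 2 it recovered 65.7, 97.0 and 97.0% of changed genes at 1 h, 52.2, 91.0 and 95.5% at 2 h, 62.7, 98.5 and 100% at 4 h, and 92.5, 100 and 100% for the average. For isopropanol at 4 h it recovered 64.2, 98.5 and 97.0%. Of its calls 2.25 to 6.49% were false, and it made 0 calls where no change was simulated. The simulated noise was independent between arrays and equally wide in every group, as the model assumes. On the real arrays the standard deviation of replicate differences ran from 0.105 to 0.239, and replicate deviations were correlated. The simulation therefore checks the calculation and does not give the error rates in these data.

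The other settings were a replicate block, a trended and robust variance, cyclic loess, median centring, quantile normalization of the tested probe sets, leaving out the dimmest 25% of the probe sets (no fission yeast probe sets were present to set a background level), all probe sets in place of 1 per gene, and each array left out in turn. For the TFM comparisons there were also time zero or all 5 isopropanol arrays as control, only the arrays of 1 time point, no 2 h time point, an additive model and an estimated correlation. Settings chosen after seeing the data were the hybridization control level or the mean 3 prime minus 5 prime difference of 7 control transcripts as a covariate, leaving out 3 arrays with a high 3 prime minus 5 prime difference, a crossed replicate block at 1 h, a replicate block for the arrays without TFM in the isopropanol comparisons, and each array left out in turn for the heat shock and ribosome biogenesis lists in isopropanol. Probe sets without a gene were left out of the comparisons, and raw scans are not used here.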

Results

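The arrays followed BY4741 yeast, grown to saturation on glycerol and ethanol, through 1, 2 and 4 h with the lampricide TFM at 0.05 mM or with 2% isopropanol. The sample labels give no isopropanol level for the TFM arrays. A difference in isopropanol between the 2 arms is therefore not excluded. TFM, 3-trifluoromethyl-4-nitrophenol, is known to uncouple mitochondrial respiration from ATP synthesis. Each group had 2 arrays, except isopropanol at 2 h with 1, and 2 arrays stood for time zero. The labels call the RNA samples independent and do not say whether the cultures were separate, so every p below measures only the spread between these RNA samples, which may be technical. All changes are log2 differences with their standard errors, relative to the array as a whole, since the deposited values were normalized to a common distribution.

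In cells given isopropanol without TFM no gene passed the threshold in limma at 1, 2 or 4 h against time zero (0 of 5449 genes at each time). The genes of smallest p at 2 h were CTR1, the high-affinity copper transporter, at 0.90 ± 0.12 (adjusted p = 0.115), and FET4, a low-affinity iron transporter, at 0.61 ± 0.086 (adjusted p = 0.115), none passing. FRE7, a metalloreductase gene (1.19), ERO1 (0.60) and FRE1 (0.41) followed. At 1 h they were RRP36 (0.44, adjusted p = 0.567), RRT15 (1.08), FRE1 (0.41), ERO1 (0.50) and the aquaporin gene AQY1 (-0.66). At 4 h they were CTR1 (0.55, adjusted p = 0.891), FET4 (0.38), FRE1 (0.38), CIS1 (-0.33) and YOL014W (0.31). CTR1 did pass at 2 h with other settings, at 0.90 with a trended, robust variance (adjusted p = 0.0193), at 0.92 after median centring (0.0444). Together with FET4 at 0.67 it also passed after cyclic loess (adjusted p = 0.048 for both genes), and 1 gene passed with the dimmest 25% of the probe sets left out. An unadjusted p under 0.05 was reached by 367, 111 and 67 genes at 1, 2 and 4 h, beside 272 by chance. The model pooled the variance of each gene over all groups. The standard deviation of replicate differences was 0.105 at time zero and 0.151 and 0.189 in isopropanol at 1 and 4 h. It was 0.141, 0.239 and 0.221 in TFM at 1, 2 and 4 h. At 2 and 4 h the counts lay below chance, so the test may have been conservative there. The lack of calls therefore does not show that no gene changed.

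Among the gene lists, the heat shock list, targets of Hsf1, had medians of 0.25, 0.25 and 0.12 in isopropanol at 1, 2 and 4 h, with 0 of its 24 members past the threshold for single genes at any time (camera adjusted p = 5.44e-14, 7.89e-25 and 1.06e-05). These calls were lost at adjusted p = 0.635, 0.298 and 0.45 with an estimated correlation. At 4 h the median was -0.035 without isopropanol 4 h replicate 1 (camera adjusted p = 0.0412, lower), 0.21 without replicate 2 and 0.053 without time zero replicate 2, so its direction is not settled. The medians of ribosome biogenesis were -0.087 at 1 h, -0.092 at 2 h and 0.14 at 4 h (camera adjusted p = 0.0318, 0.000169 and 1.06e-20), calls lost at adjusted p = 0.859, 0.576 and 0.13 with an estimated correlation. The call at 1 h was also lost without time zero replicate 1 (median -0.062) or isopropanol 1 h replicate 2 (-0.069). In all, camera called 8, 9 and 14 of the 32 tested lists at 1, 2 and 4 h with its preset correlation and 0 with an estimated correlation, where the smallest adjusted p was 0.635, 0.298 and 0.13. With a replicate block for the arrays without TFM, whose numbers were taken to pair them on the data alone, 0 genes passed at any time. In that model 4, 5 and 13 lists were called. The block was chosen after seeing the data. In it the call of ribosome biogenesis at 1 h was lost (adjusted p = 0.0619), while those of heat shock stayed. For cytosolic ribosomal proteins at 2 h the sign of the median, 0.0072, turned under cyclic loess (-0.0068), quantile normalization (-0.0050) and the replicate block (-0.0072, camera adjusted p = 0.881).

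Every ranking of TFM changes below is among genes past the threshold. After 1 h of TFM the transcripts that rose most were those of IMA5, an alpha-glucosidase, by 2.02 ± 0.19 (adjusted p = 0.00436), and HXT1, the low-affinity glucose transporter, by 1.98 ± 0.31 (adjusted p = 0.0394). YKR075C (1.14 ± 0.15), the peroxisomal import gene PEX21 (1.05 ± 0.13) and YLR108C (0.98 ± 0.18) came next. The largest falls were in SPR3, a septin of sporulating cells (-0.92 ± 0.16), YHL009W-A (-0.86 ± 0.15), the transcription factor gene HMS1 (-0.82 ± 0.13), YOL014W (-0.71 ± 0.076, adjusted p = 0.00761) and ETP1 (-0.66 ± 0.11). In total 44 genes were higher and 23 lower at 1 h, 1.23% of the 5449 tested, and 4 of these changed at least 2-fold. Both TFM arrays lay beyond both isopropanol arrays for each of the 67 genes, which selection on the same arrays nearly ensures and which adds no evidence (chance separates 33.3% of unselected genes).

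Of the lists, hexose transporters had 4 members that rose at 1 h and 0 that fell (5 and 0 adjusted over the list alone), HXT3 among them at 0.88 ± 0.17, and the list as a whole, with a median of 0.072, missed the threshold (camera adjusted p = 0.0616). It passed in 7 of 26 other settings, among them without the dimmest 25% of the probe sets (median 0.75) and against time zero (0.20), and the lowest median was 0.037 without TFM 1 h replicate 1. The mitochondrial ribosome list was higher, with a median of 0.18, although 1 of its 55 members rose by itself and 8 adjusted over the list alone (camera adjusted p = 2.73e-09; adjusted p = 0.076 with an estimated correlation). Amino acid biosynthesis was lower, with a median of -0.078 and 1 of 41 members that fell, 2 adjusted over the list alone (camera adjusted p = 0.00888; adjusted p = 0.596 with an estimated correlation). That call was also lost without TFM 1 h replicate 1 (median -0.039) or isopropanol 1 h replicate 2 (median -0.074), while against time zero the median was -0.16 (adjusted p = 2.24e-06). The mean 3 prime minus 5 prime difference of 7 control transcripts, a sign of RNA integrity, was 1.42 and 1.34 on the isopropanol 1 h arrays and 1.32 and 1.39 on the TFM 1 h arrays.

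The count at 1 h was not stable: it fell without any single 1 h array, either time zero array or either TFM 4 h array. The time zero and TFM 4 h arrays are not in this contrast. Leaving one of them out changes no log2 change at 1 h, only the variance estimate and its degrees of freedom. The count at 1 h was 114 under cyclic loess, 118 after quantile normalization, 117 against time zero and 307 against all 5 isopropanol arrays. With settings chosen after seeing the data it was 3 with the hybridization control level and 148 with the 3 prime minus 5 prime difference as a covariate, and 13 with 3 arrays left out. Of the 10 most changed genes at 1 h, 0 kept the call without TFM 1 h replicate 1, 1 without isopropanol 1 h replicate 2, 2 without TFM 1 h replicate 2 or either time zero array, 3 without isopropanol 1 h replicate 1 and 7 without either TFM 4 h array.

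**Figure D1:**
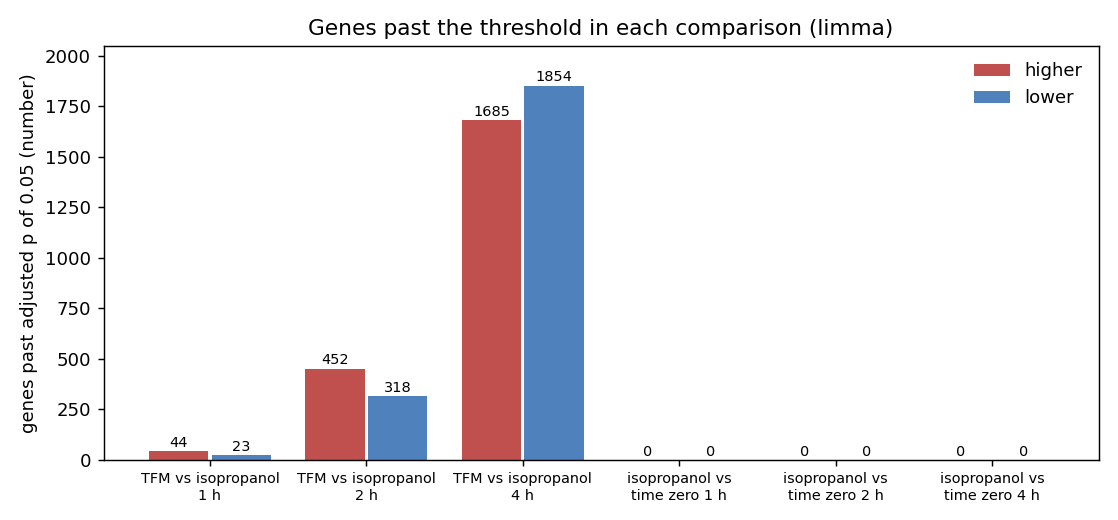
Bars give the number of genes (vertical axis) with a limma adjusted p under 0.05 in each comparison (horizontal axis), higher in red and lower in blue. The TFM counts were 44 and 23 at 1 h, 452 and 318 at 2 h, and 1685 and 1854 at 4 h, beside 0 in isopropanol against time zero.

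After 2 h of TFM IMA5 rose the most, by 3.93 ± 0.23 (adjusted p = 0.000102), followed by the glucose transporter gene HXT1, by 3.63 ± 0.38 (adjusted p = 0.00142). MIG2, a zinc-finger repressor of glucose-repressed genes, rose by 2.99 ± 0.37 (adjusted p = 0.00215). The transporter genes HXT3 and HXT8 rose by 2.71 ± 0.21 (adjusted p = 0.000232) and 2.32 ± 0.39 (adjusted p = 0.007). The largest falls were in GPD2, a glycerol 3-phosphate dehydrogenase (-1.68 ± 0.34), IME1, the master regulator of meiosis (-1.41 ± 0.16), YDL241W (-1.39 ± 0.19), HMS1 (-1.28 ± 0.16) and RRG8 (-1.24 ± 0.30). In total 452 genes were higher and 318 lower, 14.1% of those tested, and 27 and 16 of them changed at least 2-fold. The size of this excess of higher genes, and against time zero its direction, depended on the setting: 638 and 675 genes were higher and lower against time zero, 831 and 810 against all 5 isopropanol arrays, and 437 and 409 after quantile normalization. All 770 genes had both TFM arrays beyond the single isopropanol array, again nearly ensured by the selection and no added evidence (66.7% of unselected genes by chance).

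Hexose transporters had 6 members up and 0 down of 17 at 2 h (6 and 0 adjusted over the list alone). The list median was 0.24 (camera adjusted p = 0.00122; adjusted p = 0.277 with an estimated correlation). In the pleiotropic drug resistance list, targets of Pdr1 and Pdr3, 9 of 18 rose and 2 fell (10 and 2 adjusted over the list alone), among them CIS1 at 1.58 ± 0.10 and the transporter gene PDR10 at 0.86 ± 0.12. Its median stood at 0.47 (camera adjusted p = 9.34e-05; adjusted p = 0.277 with an estimated correlation). Of the beta-oxidation and peroxisome list 6 of 18 rose and 0 fell (9 and 0 adjusted over the list alone), including the thiolase gene POT1 at 1.01 ± 0.11 and the peroxisomal catalase gene CTA1 at 0.47 ± 0.089. Its median stood at 0.36 (camera adjusted p = 3e-04; adjusted p = 0.277 with an estimated correlation). Ribosome biogenesis had 17 of 60 members that rose and 1 that fell (20 and 1 adjusted over the list alone), with UTP5 at 0.55 ± 0.094 and UTP15 at 0.57 ± 0.12. This list had a median of 0.28 (camera adjusted p = 2.11e-05; adjusted p = 0.681 with an estimated correlation). Without TFM 2 h replicate 2 the hexose transporter median was 0.082, and it was 0.74 without the dimmest 25% of the probe sets and 0.082 with the 3 prime minus 5 prime difference as a covariate. The ribosome biogenesis median was 0.17 without TFM 2 h replicate 1, 0.15 against time zero and 0.16 against all 5 isopropanol arrays. The mitochondrial ribosome list also stood higher, with 2 of 55 members that rose and 0 adjusted over the list alone. As a whole the list stood at 0.13 (camera adjusted p = 0.00136; adjusted p = 0.277 with an estimated correlation).

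On the falling side at 2 h, cytosolic ribosomal proteins had 8 of 128 members that fell, 0 adjusted over the list alone. This list had a median of -0.18 (camera adjusted p = 1.17e-08; adjusted p = 0.681 with an estimated correlation). Of the amino acid biosynthesis genes under Gcn4 9 of 41 fell, 10 adjusted over the list alone, such as ASN2, an asparagine synthetase, at -0.53 ± 0.091. The list median was -0.21 (camera adjusted p = 9.16e-05; adjusted p = 0.277 with an estimated correlation). In ergosterol biosynthesis 6 of 24 fell and 1 rose (7 and 1 adjusted over the list alone), with ERG2 at -0.62 ± 0.084. Its median stood at -0.20 (camera adjusted p = 0.00136; adjusted p = 0.681 with an estimated correlation). Nitrogen catabolite repressed genes had 4 of 22 members that fell, 4 adjusted over the list alone, with the ammonium permease gene MEP1 at -1.11 ± 0.11 (camera adjusted p = 0.0421; adjusted p = 0.681 with an estimated correlation). The phosphate regulon had 3 of 14 members that rose, 3 adjusted over the list alone, SPL2 among them at 1.17 ± 0.11 (camera adjusted p = 0.032; adjusted p = 0.392 with an estimated correlation). Without TFM 2 h replicate 2 the medians were -0.14 for amino acid biosynthesis, -0.13 for ergosterol biosynthesis and 0.23 for the phosphate regulon. With the 3 prime minus 5 prime covariate they were -0.12 for ergosterol biosynthesis, 0.24 for the phosphate regulon and -0.10 for cytosolic ribosomal proteins. The nitrogen call was lost without TFM 2 h replicate 1 (median -0.13) or either TFM 4 h array (-0.11), against all 5 isopropanol arrays (-0.047), without the dimmest 25% of the probe sets (-0.073) and with the hybridization control level as a covariate (-0.10). The phosphate call was lost without TFM 2 h replicate 1 (0.070), against time zero (0.069) and against all 5 isopropanol arrays (0.084).

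The control at 2 h was 1 array, assumed to vary like the other groups, and the count fell to 382 without TFM 2 h replicate 2 and to 485 without either time zero array. RRG8 lost its call without TFM 2 h replicate 2 (-0.96, adjusted p = 0.101), and GPD2 against all 5 isopropanol arrays (-0.55, adjusted p = 0.354) or time zero (-0.70, adjusted p = 0.0964). TFM 2 h replicate 2 had a mean 3 prime minus 5 prime difference of 1.49, beside 1.18 on replicate 1 and 1.14 on the isopropanol array.

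After 4 h of TFM 1685 genes were higher and 1854 lower than in isopropanol, 65.0% of the 5449 tested. With the 3 prime minus 5 prime difference as a covariate, a setting chosen after seeing the data, the counts were 1152 and 1292. Under cyclic loess they were 1825 and 1790 and without isopropanol 4 h replicate 2 they were 1605 and 1589, so the balance of higher and lower genes is not settled. At least 2-fold changes were 262 and 341 of these. The largest rises were in MIG2 by 4.45 ± 0.30 (adjusted p = 2.41e-06), HXT1 by 4.4 ± 0.31 (adjusted p = 2.98e-06) and YOR338W by 4.29 ± 0.20 (adjusted p = 5.99e-07). They were followed by HXT3 by 3.82 ± 0.17 (adjusted p = 5.99e-07) and STR3, a cystathionine beta-lyase gene, by 3.57 ± 0.18 (adjusted p = 7.55e-07). Among genes above background YOL014W fell the most, by 2.81 ± 0.082 (adjusted p = 7.37e-08), followed by PHO11, an acid phosphatase gene (-2.30 ± 0.12). URA7, a CTP synthase gene (-2.29 ± 0.14), UTR2, a cell wall transglycosylase gene (-2.19 ± 0.20), and RPS0B of the small ribosomal subunit (-2.19 ± 0.19) came next. MF(ALPHA)1, the alpha-factor precursor gene (-2.50 ± 0.16), ended at the level of the background control probe sets, so its fall is a lower bound and its rank is open. Each of the 3539 genes had both TFM arrays beyond both isopropanol arrays, likewise nearly ensured by the selection and no added evidence (33.3% of unselected genes by chance). The mean 3 prime minus 5 prime difference moved with the same groups: it was 1.63 and 1.40 on the TFM 4 h arrays and 1.15 and 1.13 on the isopropanol 4 h arrays. The hybridization control level was 12.2 on TFM 4 h replicate 1 and 11.4, 11.5 and 11.3 on the other 3 arrays.

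**Figure D2:**
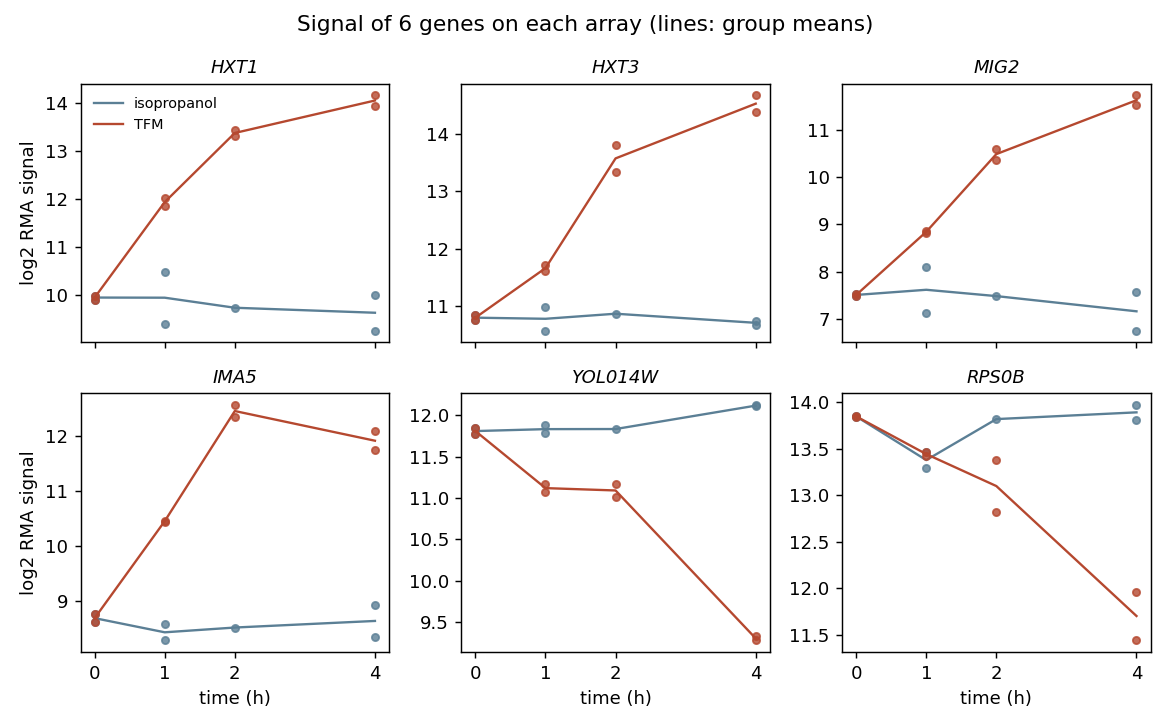
Points give the log2 RMA signal of 6 genes on each array (vertical axis) against time in hours (horizontal axis), lines join group means, and the time zero arrays belong to both courses. HXT1, HXT3, MIG2 and IMA5 stood 4.4, 3.82, 4.45 and 3.27 above isopropanol at 4 h, while YOL014W and RPS0B stood at -2.81 and -2.19.

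Camera called the cytosolic ribosomal protein, ribosome biogenesis and mitochondrial ribosome lists lower at 4 h with its preset correlation, and none of them with an estimated correlation. Of the 128 measured cytosolic ribosomal protein genes 122 fell and 0 rose (126 and 0 adjusted over the list alone), with a median of -0.83, RPS26B at -1.82 ± 0.070 and RPL22A at -1.67 ± 0.082 (camera adjusted p = 1.11e-22; adjusted p = 0.423 with an estimated correlation). In ribosome biogenesis 42 of 60 fell and 9 rose (43 and 9 adjusted over the list alone), with the box C/D snoRNP gene NOP58 at -1.30 ± 0.066 and KRR1 at -1.70 ± 0.14 on one side and UTP15 at 0.68 ± 0.094 and UTP5 at 0.64 ± 0.077 on the other. This list had a median of -0.63 (camera adjusted p = 2.18e-05; adjusted p = 0.427 with an estimated correlation). The mitochondrial ribosome list was lower at this time, with 27 of 55 members that fell and 6 that rose (26 and 5 adjusted over the list alone), MRPS28 at -0.83 ± 0.088 and MRP20 at 0.81 ± 0.086. As a whole the list stood at -0.19 (camera adjusted p = 0.0415; adjusted p = 0.423 with an estimated correlation). Without TFM 4 h replicate 2 the mitochondrial ribosome median was -0.11. The list call was lost without isopropanol 4 h replicate 1 (median -0.19), under cyclic loess (-0.15), against time zero (-0.13), with the 3 prime minus 5 prime difference as a covariate (-0.21) and without the dimmest 25% of the probe sets (-0.19).

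The ergosterol biosynthesis and a-specific lists were called lower at 4 h with the preset correlation only. In ergosterol biosynthesis 19 of 24 fell and 1 rose, the same counts adjusted over the list alone, with ERG2 at -1.40 ± 0.069, ERG6 at -1.15 ± 0.065 and, on the rising side, IDI1 at 0.67 ± 0.088. The list median was -0.53 (camera adjusted p = 0.000249; adjusted p = 0.424 with an estimated correlation). All 7 a-specific genes, those of the mating type of BY4741, fell, also when adjusted over the list alone, among them the a-factor gene MFA1 (-1.11 ± 0.067) and ASG7 (-1.63 ± 0.15). As a whole the list stood at -1.11 (camera adjusted p = 0.000624; adjusted p = 0.422 with an estimated correlation). Of the 4 alpha-specific genes, too few to test as a list, SAG1 rose (0.96 ± 0.074) and MF(ALPHA)1 fell, counts that were the same adjusted over the list alone.

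Higher at 4 h with the preset correlation only were the lists of hexose transporters, the glyoxylate cycle and gluconeogenesis, beta-oxidation and peroxisome, and the retrograde response. In hexose transporters 9 of 17 rose and 3 fell, the same counts adjusted over the list alone, from HXT1 and HXT3 through HXT4 (2.14 ± 0.21) and the glucose sensor gene SNF3 (1.23 ± 0.071) to HXT9 (-0.91 ± 0.080) and HXT10 (-0.51 ± 0.12). The list median was 0.52 (camera adjusted p = 0.0415; adjusted p = 0.424 with an estimated correlation). That list call was lost without TFM 4 h replicate 1 (median 0.45), under cyclic loess (0.53) and quantile normalization (0.50), and with the hybridization control level (0.43) or the 3 prime minus 5 prime difference (0.35) as a covariate. Its median was 1.23 without the dimmest 25% of the probe sets. Of the glyoxylate cycle and gluconeogenesis genes 11 of 15 rose and 0 fell (12 and 0 adjusted over the list alone), with the transcription factor gene SIP4 at 1.24 ± 0.069 and ICL2 at 1.02 ± 0.064. Its median stood at 0.33 (camera adjusted p = 0.000777; adjusted p = 0.287 with an estimated correlation). Beta-oxidation and peroxisome genes had 13 of 18 members that rose and 1 that fell (14 and 1 adjusted over the list alone), POT1 at 1.67 ± 0.089 and CTA1 at 1.05 ± 0.072. This list had a median of 0.67 (camera adjusted p = 0.000327; adjusted p = 0.41 with an estimated correlation). All 8 retrograde response genes rose, also when adjusted over the list alone, such as DLD3 at 1.25 and CIT2, the peroxisomal citrate synthase gene, at 0.35, both chosen after their values were seen. As a whole the list stood at 0.44 (camera adjusted p = 0.00607; adjusted p = 0.423 with an estimated correlation).

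The nitrogen catabolite repressed, sulfur assimilation and methionine, iron regulon and pleiotropic drug resistance lists were also called higher with the preset correlation only. Of the nitrogen catabolite repressed genes 16 of 22 rose and 3 fell, the same counts adjusted over the list alone, with the ammonium permease gene MEP2 at 2.51 ± 0.23, the urea transporter gene DUR3 at 2.15 ± 0.15 and DAL80 at 1.12 ± 0.11. The list median was 0.78 (camera adjusted p = 0.000532; adjusted p = 0.422 with an estimated correlation). In sulfur assimilation and methionine 12 of 20 rose and 4 fell, the same counts adjusted over the list alone, with STR3, MET2 at 2.11 ± 0.10 and, falling, SAM2 at -1.02 ± 0.12. Its median stood at 0.60 (camera adjusted p = 0.0166; adjusted p = 0.424 with an estimated correlation), a call lost without the dimmest 25% of the probe sets (median 0.51). In the iron regulon 11 of 22 rose and 4 fell, the same counts adjusted over the list alone. The iron-sulfur scaffold genes ISU1 (1.00 ± 0.083) and ISU2 (1.10 ± 0.093) were among the first and the siderophore transporter genes ENB1 (-0.66 ± 0.089) and ARN2 (-0.55 ± 0.078) among the second. This list had a median of 0.30 (camera adjusted p = 0.0415; adjusted p = 0.577 with an estimated correlation). The iron call was lost without isopropanol 4 h replicate 1 (median 0.23), TFM 4 h replicate 2 (0.30) or either TFM 2 h array (0.30), after quantile normalization (0.31) and without the dimmest 25% of the probe sets (0.27). Of the pleiotropic drug resistance genes 15 of 18 rose and 1 fell (15 and 2 adjusted over the list alone), with CIS1 at 2.54 ± 0.082, PDR10 at 1.32 ± 0.096 and RTA1 at -0.99 ± 0.17. As a whole the list stood at 0.43 (camera adjusted p = 0.000835; adjusted p = 0.41 with an estimated correlation).

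**Figure D3:**
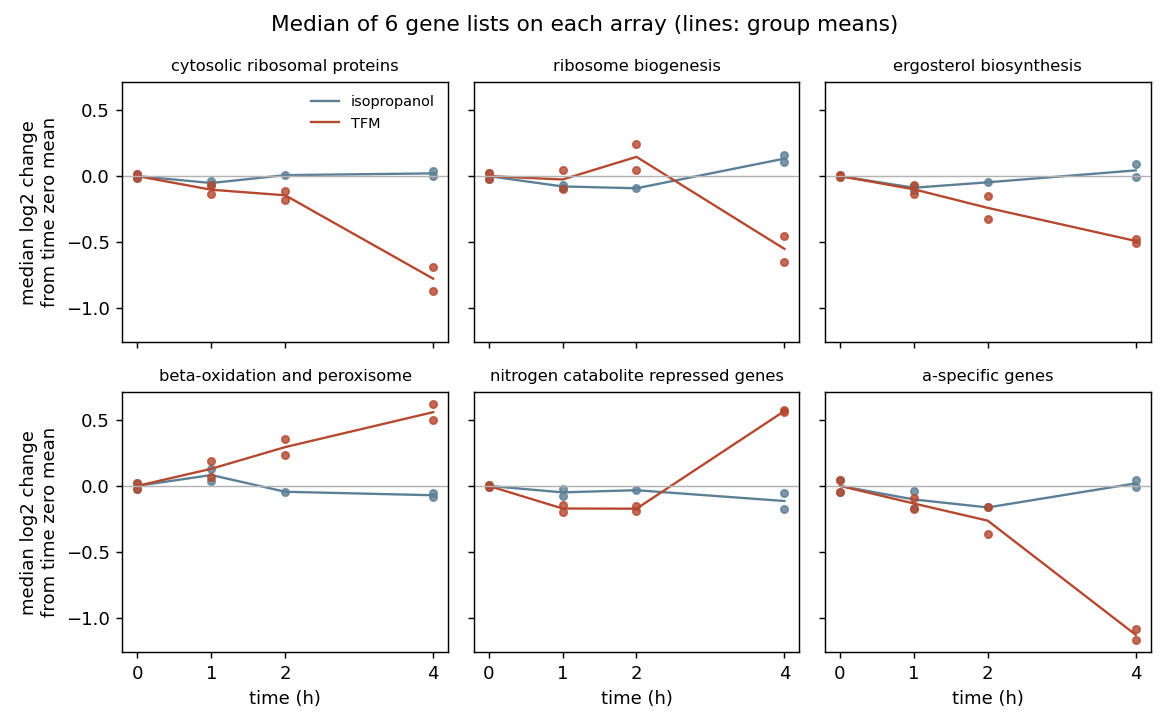
Points give the median log2 change from the time zero mean over the members of 6 gene lists on each array (vertical axis) against time in hours (horizontal axis), and lines join group means. At 4 h the median TFM change against isopropanol was -0.83 for cytosolic ribosomal proteins, -0.63 for ribosome biogenesis, -0.53 for ergosterol biosynthesis, 0.67 for beta-oxidation and peroxisome, 0.78 for nitrogen catabolite repressed genes and -1.11 for a-specific genes.

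Camera called none of the lists of respiration, glycolysis or sugar storage at 4 h, although genes of each passed. In the respiratory chain 4 of 25 rose and 6 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.975), with the external NADH dehydrogenase gene NDE2 at 0.90 ± 0.14 and the cytochrome c gene CYC1 at -1.21 ± 0.12. Of the ATP synthase genes 0 of 17 rose and 7 fell (0 and 6 adjusted over the list alone; adjusted p = 0.39). In the tricarboxylic acid cycle IDH1 rose (0.21 ± 0.067) and KGD2 fell (-0.17 ± 0.057) of 11 genes, 0 adjusted over the list alone (adjusted p = 0.975). The IDH1 call was lost without TFM 4 h replicate 1 or isopropanol 4 h replicate 1 (0.18 each), and the KGD2 call without TFM 4 h replicate 1 (-0.16), isopropanol 4 h replicate 1 (-0.17) or isopropanol 4 h replicate 2 (-0.18). Glycolysis had 8 of 20 genes that fell and 2 that rose, the same adjusted over the list alone (adjusted p = 0.265), the phosphofructokinase gene PFK1 at -0.83 ± 0.069. In trehalose and glycogen 9 of 18 fell and 3 rose, the same adjusted over the list alone (adjusted p = 0.209), the phosphoglucomutase gene PGM1 at -1.42 ± 0.11 and the trehalase gene ATH1 at 0.92 ± 0.11.

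Camera called none of the following lists at 4 h. In general stress 4 of 24 rose and 6 fell, the same adjusted over the list alone (adjusted p = 0.975), with RTN2 at -0.78 ± 0.082 and SPI1 at 0.37 ± 0.066. In heat shock 4 of 24 rose and 3 fell (4 and 2 adjusted over the list alone; adjusted p = 0.699), with the Hsp70 gene SSA3 at 1.23 ± 0.087, HSF1 at 0.96 ± 0.11 and the Hsp90 gene HSC82 at -0.57 ± 0.083. In oxidative stress 9 of 24 rose and 8 fell, the same adjusted over the list alone (adjusted p = 0.975), from the exporter gene ATR1 (1.26 ± 0.15) to GND1 (-1.24 ± 0.066) and the peroxiredoxin gene TSA2 (-1.21 ± 0.15). Of the oxidoreductases and glutathione transferases 9 of 19 rose and 6 fell, the same adjusted over the list alone (adjusted p = 0.364), with ARI1 at 1.95 ± 0.24 and GTT2 at 0.73 ± 0.082. The weak acid response had 3 of 12 that rose and 1 that fell (2 and 1 adjusted over the list alone; adjusted p = 0.717). The unfolded protein response had 9 of 15 that fell and 3 that rose, the same adjusted over the list alone (adjusted p = 0.149), with MPD1 at -1.03 ± 0.078 and ERO1 at 1.03 ± 0.10. In the proteasome 9 of 32 rose and 3 fell (7 and 3 adjusted over the list alone; adjusted p = 0.525), with its transcription factor gene RPN4 at 0.94 ± 0.079. In autophagy 7 of 20 rose and 2 fell, the same adjusted over the list alone (adjusted p = 0.366), with ATG11 at 1.44 ± 0.077 and ATG10 at -0.74 ± 0.083.

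The other lists were not called at 4 h either. In amino acid biosynthesis 19 of 41 fell and 10 rose, the same adjusted over the list alone (adjusted p = 0.253), with LYS9 at -1.07 ± 0.068 and CPA1 at 1.34 ± 0.069. The phosphate regulon had 5 that rose and 5 that fell of 14, the same adjusted over the list alone (adjusted p = 0.975), with PHO8 at 0.69 ± 0.076 beside PHO11. In hypoxic genes 5 of 16 rose and 7 fell, the same adjusted over the list alone (adjusted p = 0.717), with the fatty acid desaturase gene OLE1 at 1.72 ± 0.093 and the mannoprotein gene TIR1 at -2.14 ± 0.095. Of 9 histone genes 1 rose and 2 fell, the same adjusted over the list alone (adjusted p = 0.717), HTZ1 at 0.32 ± 0.061 and HHO1 at -1.13 ± 0.088. In cyclins and cell cycle 11 of 21 fell and 5 rose, the same adjusted over the list alone (adjusted p = 0.311), with the mitotic genes CLB2 at -1.64 ± 0.17 and SWI5 at -1.45 ± 0.069 and the G1 cyclin gene CLN1 at 0.86 ± 0.064. Meiosis and sporulation had 4 that rose and 4 that fell of 16, the same adjusted over the list alone (adjusted p = 0.996), DIT2 at 1.25 ± 0.15 and SPR3 at -1.12 ± 0.16. The genes deleted in BY4741 gave 0 calls of 4, also adjusted over the list alone, with LEU2, MET17 and URA3 at background and HIS3, whose deletion is partial, above it. None of the 8 mitochondrially encoded genes was matched to a probe set, and they are not analysed here. Median, mean and test differed in sign for 4 lists at 4 h, the tricarboxylic acid cycle, general stress, oxidative stress and meiosis and sporulation, and for none that camera called in any comparison.

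With an estimated correlation camera called 0 of the 32 lists at 4 h, where the smallest adjusted p was 0.287, against 13 with the preset correlation. No array left out alone moved the count of genes at 4 h by over 1.5 times.

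Averaged over the 3 time points, 1508 genes were higher and 1539 lower with TFM, 55.9% of those tested. The largest mean rises were in HXT1 (3.34 ± 0.20, adjusted p = 4.12e-06), IMA5 (3.07 ± 0.12, adjusted p = 5.13e-07), MIG2 (2.89 ± 0.19), HXT3 (2.47 ± 0.11) and YKR075C (2.29 ± 0.094). YOR338W (2.26 ± 0.12), YLR108C (1.75 ± 0.11), HXT8 (1.73 ± 0.20), HXT4 (1.70 ± 0.13) and OPT1, a glutathione and oligopeptide transporter gene (1.68 ± 0.098), followed. The largest mean falls were in YOL014W (-1.42 ± 0.047, adjusted p = 2.35e-07), UTR2 (-1.20 ± 0.12) and YDL241W (-1.11 ± 0.098). IME1 (-0.99 ± 0.083), HMS1 (-0.95 ± 0.083), RPS0B (-0.95 ± 0.12), the transcription factor gene YAP6 (-0.94 ± 0.066) and COS6 (-0.93 ± 0.13) followed. MF(ALPHA)1 (-1.14 ± 0.10) and BSC1 (-1.12 ± 0.22) were at background in at least 1 group, so their falls are lower bounds without a rank. Camera called 7 of 32 lists: hexose transporters (median 0.32, adjusted p = 0.0193; adjusted p = 0.415 with an estimated correlation), beta-oxidation and peroxisome (0.36, 0.000317; adjusted p = 0.415 with an estimated correlation) and pleiotropic drug resistance (0.31, 0.000535; adjusted p = 0.415 with an estimated correlation) were higher. Cytosolic ribosomal proteins (-0.37, 4.75e-21; adjusted p = 0.415 with an estimated correlation), ergosterol biosynthesis (-0.26, 7e-04; adjusted p = 0.635 with an estimated correlation), amino acid biosynthesis (-0.18, 0.0119; adjusted p = 0.448 with an estimated correlation) and a-specific genes (-0.41, 0.00555; adjusted p = 0.415 with an estimated correlation) were lower. Members that rose and fell numbered 9 and 2, 15 and 1, 14 and 2, 1 and 115, 2 and 16, 4 and 22, and 0 and 6 in these 7 lists in that order. Adjusted over the list alone they numbered 9 and 2, 15 and 1, 14 and 2, 1 and 118, 2 and 17, 6 and 22, and 0 and 6. An additive model of time and agent over the 11 arrays after time zero called 1502 genes, and in it the calls of RPS0B (-0.98, adjusted p = 0.0539) and of the a-specific list (median -0.44) were lost. The amino acid call was lost without the 2 h time point (median -0.14), and the hexose transporter call with the 3 prime minus 5 prime covariate (0.20) or without 3 arrays of a high 3 prime minus 5 prime difference (0.23). Without TFM 2 h replicate 2 the hexose transporter median was 0.21, and without the dimmest 25% of the probe sets 0.93.

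The TFM effect itself differed between 4 h and 1 h for 2684 genes, 49.3% of those tested, with 1247 higher and 1437 lower at 4 h by the test of the difference in limma. The largest differences were in YOR338W (3.53 ± 0.28, adjusted p = 4.44e-05), MIG2 (3.23 ± 0.43), MEP2 (3.03 ± 0.33), STR3 (2.98 ± 0.25) and HXT3 (2.94 ± 0.24) on the higher side. On the lower side they were in RPS0B (-2.25 ± 0.27, adjusted p = 0.000196), URA7 (-2.18 ± 0.20), RRP3, an RNA helicase gene of ribosome assembly (-2.13 ± 0.21), and PHO11 (-2.11 ± 0.17). For MF(ALPHA)1 the difference of -2.24 ± 0.23 is a lower bound in size, since the gene was at background at TFM 4 h, and its rank is open. Camera called 11 lists for this difference, among them cytosolic ribosomal proteins (median -0.76, adjusted p = 1.17e-22; adjusted p = 0.4 with an estimated correlation), nitrogen catabolite repressed genes (0.87, 3.83e-05; adjusted p = 0.27 with an estimated correlation) and the mitochondrial ribosome (-0.33, 0.000173; adjusted p = 0.27 with an estimated correlation), and 0 with an estimated correlation. Of the 128 cytosolic ribosomal protein genes 110 were lower at 4 h than at 1 h by this test and 0 higher (115 and 0 adjusted over the list alone). With the 3 prime minus 5 prime difference as a covariate, an alternative chosen after seeing the data, 1618 genes differed.

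Most genes called early were called again later, but 65.0% of all tested genes were called at 4 h. Of the 44 genes higher at 1 h, 39 were higher at 2 h (3.65 expected if independent). Of the 23 lower genes 22 were lower at 2 h (1.34 expected). At 4 h 36 of the 44 were higher (13.6 expected) and 2 lower. Of the 23 lower genes 11 were lower at 4 h, near the 7.83 expected, and 3 higher. Of the 452 genes higher at 2 h, 327 were higher (140 expected) and 45 lower at 4 h. Of the 318 lower genes 251 were lower (108 expected) and 14 higher. The log2 changes correlated across genes at r = 0.561 between 1 and 2 h, 0.303 between 1 and 4 h and 0.584 between 2 and 4 h (Spearman 0.522, 0.265 and 0.555), and genes are not independent replicates. These 3 comparisons shared no array but shared the variance estimate of each gene, so their calls are not independent. Two-sided Fisher's exact tests gave p = 0.187 for the genes lower at 1 h and at 4 h. For every other overlap they gave p of 3.67e-12 or less. Since neither the calls nor the genes are independent, these p-values only describe the overlaps.

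**Figure D4:**
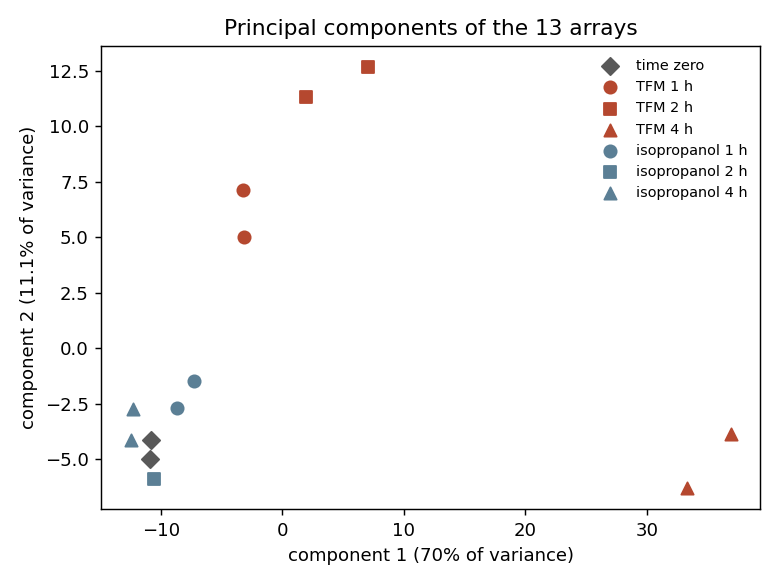
Each point is an array, placed by the first principal component (horizontal axis, 70% of the variance) and the second (vertical axis, 11.1%), both in log2 units, with color for agent and shape for time. The TFM 4 h arrays lay at 36.9 and 33.3 on the first component, and the other 11 arrays between -12.4 and 7.06.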

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

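The tests with the 3 prime minus 5 prime covariate were chosen only after the result was seen, and so were the uses of leaving out TFM 4 h replicate 1 and of all 5 isopropanol arrays as tests of an explanation, while these 2 settings, the contrast of 4 h and 1 h, and the tests of coding length and of other splits were planned. By the test of the difference, the TFM effect was higher at 4 h than at 1 h for 1247 genes and lower for 1437, and camera called 11 lists for it with its preset correlation and 0 with an estimated correlation (smallest adjusted p = 0.234). The genes that differed most were YOR338W (3.53), MIG2 (3.23), MEP2 (3.03), STR3 (2.98) and HXT3 (2.94) on the higher side and RPS0B (-2.25), URA7 (-2.18), RRP3 (-2.13) and PHO11 (-2.11) on the lower side, as log2 differences, beside MF(ALPHA)1 (-2.24, a lower bound in size, since it was at background at TFM 4 h). Counted by calls, 60 genes passed at 1 or 2 h in one direction and at 4 h in the other. Among the 218 probe sets without a gene name, which no comparison used, 70 were higher and 72 lower at TFM 4 h. This is about the share among the tested genes, 1685 and 1854 of 5449. Among the control probe sets, also outside the comparisons, the 3 prime minus 5 prime difference averaged 0.91 for ACT1 on the TFM 4 h arrays, beside 0.25 to 0.57 on the other 11, and 0.029 for RIP1, beside -0.35 to -0.05. These were the 2 of 7 control transcripts for which both TFM 4 h arrays lay above all others. Between the TFM 4 h and isopropanol 4 h means, SRB4 (1.04) and WBP1 (0.67) differed more than ACT1 (0.62) and RIP1 (0.33). Their TFM 4 h values overlapped with those of other arrays. The same difference was 0.11 for EAF5, -0.13 for SPT15 and -0.0033 for TDH1.

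The size of the change at 4 h, 3539 genes, was weighed first, against RNA degradation, the labelled RNA on 1 array and a loss of long transcripts. In a model with a mean for each group, the slope of the 3 prime minus 5 prime covariate rests only on differences between replicates. These were largest at TFM 2 h (1.18 and 1.49) and TFM 4 h (1.63 and 1.40). Any other difference between those replicates enters the slope too, so the covariate cannot decide how far degradation is a cause, and it stays open. With the covariate 2263 of the 3539 genes (63.9%) kept their call and direction. Without TFM 4 h replicate 1, the array with the high hybridization control level, 3024 of the 3539 kept theirs, and the Spearman correlation across genes of the 4 h change with coding length was 0.121, where a loss of long transcripts needs a negative one. That correlation runs over all genes, and other changes related to length can move it, so a loss among some long transcripts is not excluded. For the average over time points, 1 of 100 splits of the 11 arrays within their time points (of 108 possible), the real one, gave as many genes, 3047 beside 2708 in the highest other split. The result rests on the 4 h arrays: splits that exchanged 1 TFM 4 h array gave 0 genes, while the split with 2708 exchanged both. It thus followed the likeness of the 4 h replicates. As these may be RNA samples of 1 culture, the splits cannot tell TFM from a difference between cultures, and no conclusion is drawn from them. A biological response to TFM over 4 h remains a hypothesis, and an unequal change in total mRNA stays open, since the normalization hides it.

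The second pattern is ribosome biogenesis, higher at 2 h (17 of 60 rose, 1 fell) and lower at 4 h (42 fell, 9 rose). With the 3 prime minus 5 prime covariate the median was 0.36 at 2 h and -0.54 at 4 h, beside 0.28 and -0.63 without it, and so kept its sign. Both adjusted medians lay beyond 2 times the standard error of the difference between the arrays (0.23 and 0.094). That standard error was taken without the covariate, so it does not measure the error of the adjusted medians, and 3 prime bias is not excluded. Against all 5 isopropanol arrays the median at 2 h was 0.16, within 2 times the standard error (0.22), and from the time zero mean the TFM 2 h arrays stood at 0.25 and 0.045 beside 0.11 and 0.16 on the isopropanol 4 h arrays. The single isopropanol 2 h array therefore stays open as a cause of the rise at 2 h, and no biological reading of it is offered. Camera with an estimated correlation called the list at neither time, and at 2 h a shared fluctuation of these genes between RNA samples stays open. At 4 h the TFM arrays stood at -0.65 and -0.45 from the time zero mean, beside 0.11 and 0.16 in isopropanol. The standard deviation of the list median between replicates was 0.070. These values argue against such a fluctuation between RNA samples at 4 h. A difference between cultures stays open, since the replicates may share a culture.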

How the results depend on the processing

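The spike, integrity, 3-array and crossed-block alternatives and the block for arrays without TFM below were chosen only after the results were seen, as tests added to the planned ones. The count at 4 h and the average over time points stayed within 1.5 times under every alternative run, except the additive model, which called 1502 genes on average. The 1 h count of 67 became 7 with the replicate block, 114 with cyclic loess, 118 with quantile normalization, 117 against time zero, 307 against all 5 isopropanol arrays, 3 with the hybridization spike covariate, 148 with the integrity covariate and 13 with 3 arrays left out. The 2 h count of 770 became 487 with the replicate block, 1313 against time zero, 1641 against all 5 isopropanol arrays, 513 with the integrity covariate and 399 with 3 arrays left out. Isopropanol at 2 h gave 1 gene with the trended, robust variance, 2 with cyclic loess, 1 with median centring and 1 without the dimmest 25%. The difference between 4 h and 1 h gave 1618 genes with the integrity covariate, and the lists called on average numbered 12 without the 2 h time point and 0 with an estimated correlation. With 1 array left out the counts ranged from 1 to 95 at 1 h, 382 to 893 at 2 h, 3145 to 3602 at 4 h, 2768 to 3099 on average, 2244 to 2771 for the difference, 0 to 0 in isopropanol at each time, and 7 to 8 for the lists. A crossed pairing of the replicates at 1 h gave 35 genes. In the 12 pairs of groups with TFM replicate deviations correlated at -0.471 to 0.065, so the replicate numbers were not taken to pair the TFM samples. The -0.471 was between TFM 2 h and TFM 4 h, so a factor shared across the numbers is not excluded. The mean 3 prime minus 5 prime difference was 1.18 and 1.49 on TFM 2 h replicates 1 and 2. It was 1.63 and 1.40 on TFM 4 h replicates 1 and 2. The replicate block for the arrays without TFM gave 0 genes in isopropanol at 1, 2 and 4 h and changed no call of a named gene there. SFC1 averaged over time points turned to 0.021 without the 2 h time point. Of 14522 comparisons for named genes 13497 counted as unchanged, 523 lost the call, 184 gained it, 317 moved and 1 called result turned. Of 3260 for lists 2916 counted as unchanged, 32 lost the call, 67 gained it, 245 moved and 0 called results turned. Unchanged means a call kept in its direction or, without a call, a shift within the standard deviation between replicates. The sign of uncalled results was not checked. For example, the retrograde response median at 1 h ran from -0.066 to 0.016 while all 26 settings counted as unchanged. Leaving out an array outside a comparison could not change its log2 change. The cause of these shifts was not tested. The 2 h comparison and the average were not run without the lone isopropanol 2 h array, which is their control. For the 72 genes at or under the background level, signal over background limits what can be seen, and falls to it are lower bounds.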

Other observations

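The genes named here and the tests of cross-hybridization and of glucose-like repression were chosen only after the result was seen, while the contrasts and gene lists were planned. Of the 59 genes called at 2 h and oppositely at 4 h, 45 were higher and then lower, and 7 of these 59 were in the ribosome biogenesis list, which has 60 members: ERB1 (0.62 at 2 h and -0.91 at 4 h), NOP12 (0.40 and -1.09), UTP21 (0.48 and -1.04), SPB1 (0.79 and -0.53), SSF1 (0.47 and -0.37), RRP12 (0.51 and -0.52) and UTP8 (0.49 and -0.48). Outside that list the assembly gene RIX1 (0.56 and -1.29), the RNA helicase gene MTR4 (0.45 and -1.29), the RNA polymerase I subunit gene RPA43 (0.52 and -1.31) and the oxidoreductase gene OYE3 (0.89 and -0.53) went the same way. The 14 that were lower and then higher included DLD3 (-0.84 and 1.25), the carnitine acetyltransferase gene YAT2 (-0.64 and 1.46), the amino acid permease gene GAP1 (-0.70 and 0.85), the glutamine synthetase gene GLN1 (-0.69 and 0.71) and GZF3 (-0.53 and 0.81). Of the 5 genes called at 1 h and oppositely at 4 h, PNT1 and AQY1 were higher first (0.45 and -0.25; 0.72 and -0.53), and NGL3, FET4 and DLD3 lower first (-0.57 and 0.84; -0.48 and 0.20; -0.61 and 1.25). In isopropanol against time zero AQY1 was lower at 1 h and FET4 higher at 2 and 4 h, none passing. For AQY1 and FET4 part of the difference may therefore lie in the control. These genes were chosen after their values were seen, and the calls at 2 h share the single isopropanol array.

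In medium without added glucose 9 of 17 hexose transporters rose and 3 fell at 4 h in limma (a list call lost at adjusted p = 0.424 with an estimated correlation and in 5 of 26 settings), while MIG2, STD1 (1.89 ± 0.089 at 4 h, adjusted p = 6.5e-07) and YKR075C rose. Cross-hybridization could raise several HXT signals from 1 transcript and stays open: the median at 4 h of MIG2, STD1 and YKR075C was 3.48, but these genes are part of the pattern and say nothing about the HXT probes. One hypothesis is a state like that in glucose, where gluconeogenic genes are repressed. Against it at 4 h, 0 of the 15 genes of the glyoxylate cycle and gluconeogenesis list fell in limma and 11 rose. ICL1 (0.41), PCK1 (0.23), ADY2 (0.77) and JEN1 (0.30) were among these, while FBP1 (0.16, adjusted p = 0.0566) did not pass. At 2 h the list median was -0.031 (camera adjusted p = 0.61). ICL1 (-0.34), FBP1 (-0.26) and ADY2 (0.073) did not pass in limma at 2 h, so the hypothesis is not decided for that time. MTH1, a gene repressed by glucose and chosen after its value was seen, also rose (2.72 ± 0.24, adjusted p = 9.33e-06). Signalling through the glucose sensors was not tested, and sugar levels were not measured in these data.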
